A study of Mus musculus with 6 samples.

How the data were processed

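Human cells recovered from the tracheas of 6 mouse recipients were measured by droplet single-cell RNA sequencing, with 2 libraries in each of 3 groups (primary BC, KOLF2 iBC, BU3-NGPT iBC). Groups and recipient numbers were taken from the sample titles. The deposited tables hold raw UMI counts per gene and barcode, as whole numbers without normalization. The submitters' processing notes name Cell Ranger, Seurat and the build GRCh38, and their versions and the filters applied are not given in the sources used here. The feature tables hold 58397 features, human genes with EGFP and tdTomato sequences, and no mouse genes, so mouse RNA is counted wherever it matches a human gene. The libraries hold 13364 barcodes in total, and mouse barcodes are still among them.

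Before the data were examined, limits of at least 1000 detected genes and at most 20% mitochondrial UMIs were fixed, together with the markers, gene lists, tests and naming rule. A set of 136 sex-linked features was left out of clustering and of every table. Scrublet, run per library in scanpy 1.11.5 (Python 3.11.15) with an expected rate of 6%, marked 33 of 4305 barcodes as doublets, which were removed. Counts were scaled to 10000 per barcode and log-transformed, and 2000 variable genes, 30 principal components and 15 neighbours entered Leiden clustering at resolution 1.0 (leidenalg 0.10.2), without integration. Clusters with a median of under 1% human mitochondrial UMIs, in which over 50% of barcodes had no HLA class I UMI, were set aside as mouse-like. The other clusters were named only with at least 3 markers of a class among their 100 leading genes, and clusters of 1 class were pooled.

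Several choices were made after the data were seen. A mouse index was computed as the share of a barcode's UMIs on 388 genes detected in at least 20% of mouse-like barcodes and at least 20-fold higher there than in human ones, with over 0.5 UMIs per 10000. Barcodes under 1% were taken as human, and barcodes at or above 1% with at least 5% mitochondrial UMIs as mixed. The classes were compared on human barcodes with up to 40% mitochondrial UMIs, and a library entered a class comparison with at least 5 cells. The KOLF2 against primary BC comparisons were added because the planned gene and list tests within classes, which asked for 20 cells of a class per library, had no class that reached this in both libraries of each group. The BU3-NGPT libraries held 1 and 2 human cells and entered comparisons of shares only.

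Shares of cells were compared by exact permutation tests over libraries (scipy 1.17.1), and intervals for single libraries are exact Clopper-Pearson intervals at 95%. For genes, UMI counts were summed per library and class and tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM scaling, filterByExpr with a minimum count of 10, Benjamini-Hochberg at 5%). Total counts per library in these sums ran from 142314 to 2296959. Low totals limit the precision of genes with few UMIs, so a gene with 0 UMIs in a group is given as at least the fold against a floor of 3 UMIs over the group, and a gene with 1 to 3 UMIs as a ratio with its 95% counting interval. Fixed lists, 16 of cell types and 15 of pathways, were tested with camera (limma 3.58.1) where at least 5 genes had been tested, with a preset correlation of 0.01, then with an estimated correlation and with fry. Counts of the 2 recipients of the primary BC and of the KOLF2 group were compared to see whether 1 library had been deposited under both names. Neither pair was within sampling noise (chi-square per degree of freedom of 3.36 to 6.47). The BU3-NGPT pair was not compared.

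Named genes are the 12 largest rises and 12 largest falls past 5% without overlap between groups and with a mean log2 CPM of at least 5, a set of airway markers named whatever their test, and up to 4 members of each list that passed camera. Polymorphic HLA genes, ribosomal protein, mitochondrial and clone-named genes were left out of naming. Leading genes of a class's own clusters, and symbols that stand for 2 features, were left out of the rises and falls, a choice made after the gene tables were seen, and 1 gene that met the rule is not reported here. The gene test was tested on simulated data with 200 changed genes. It recovered 47% of 2-fold and 97% of 8-fold changes in all human cells, 33% and 96% in basal-like cells, and 18% and 89% in secretory-like cells, with 9, 0 and 1 false calls. The changed genes were drawn only from those above a minimum expected count, and counts were simulated with the spread fitted to these data. These rates therefore do not cover genes with few UMIs. Alternatives covered the size factors and Wald test of DESeq2 1.42.0, count filters, thinning, free RNA, limits on cells, doublets, clustering, class assignment, the recipient number as a block, and leaving out each library. DESeq2's size factors moved the median log2 fold change of all genes by -0.0140, 0.00727 and -0.00100 in the 3 comparisons. No coordinates are given.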

Results

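The study asked how basal cells derived from human induced pluripotent stem cells behave after transplantation into a mouse airway, next to primary human airway basal cells. Basal cells are the stem cells of the airway surface epithelium, which renew themselves and give rise to secretory and multiciliated cells. Per the labels, NSG mice, an immunodeficient strain that accepts human cells, received 2% polidocanol into the trachea, a detergent that strips the surface epithelium. At 5 hours after the detergent they received 2e6 human cells, and their tracheas were taken at 6 weeks, dissociated and sorted for the human reporter. The donor cells were primary basal cells carrying GFP (primary BC), or basal cells made from the pluripotent lines KOLF2 or BU3-NGPT (iBC) carrying tdTomato. Each of the 3 groups had 2 recipients and hence 2 libraries, 6 in all, of droplet RNA sequencing with unique molecular identifiers (UMIs).

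The libraries of primary BC recipients held 10072737 and 11185747 UMIs over 3823 and 2276 barcodes. The KOLF2 libraries held 7279403 and 7730600 UMIs over 1023 and 2423 barcodes, and the BU3-NGPT libraries 3120938 and 2818618 UMIs over 1493 and 2326 barcodes. Per the labels, reporter-negative mouse cells had been added to the sorted human cells, and in every library most barcodes carried mouse RNA counted on the human reference. Human barcodes, with no limit on quality, made up 17.3% (95% exact binomial interval 16.1% to 18.5%) and 36.0% (34.1% to 38.0%) of barcodes in the primary BC libraries. In the KOLF2 libraries they made up 22.5% (19.96% to 25.2%) and 26.0% (24.3% to 27.8%). In the BU3-NGPT libraries they made up 3.95% (3.02% to 5.07%) and 0.473% (0.236% to 0.845%). Among human barcodes with at least 1000 detected genes, EGFP transcripts were seen in 26.8% and 21.2% of those from primary BC recipients and in none of the 208 and 508 from KOLF2 recipients. The tdTomato transcript was seen in 49.5% and 36.2% of the KOLF2 barcodes and in none of the 325 and 580 from primary BC recipients. All intervals and floors cover counting error only.

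**Figure D1:**
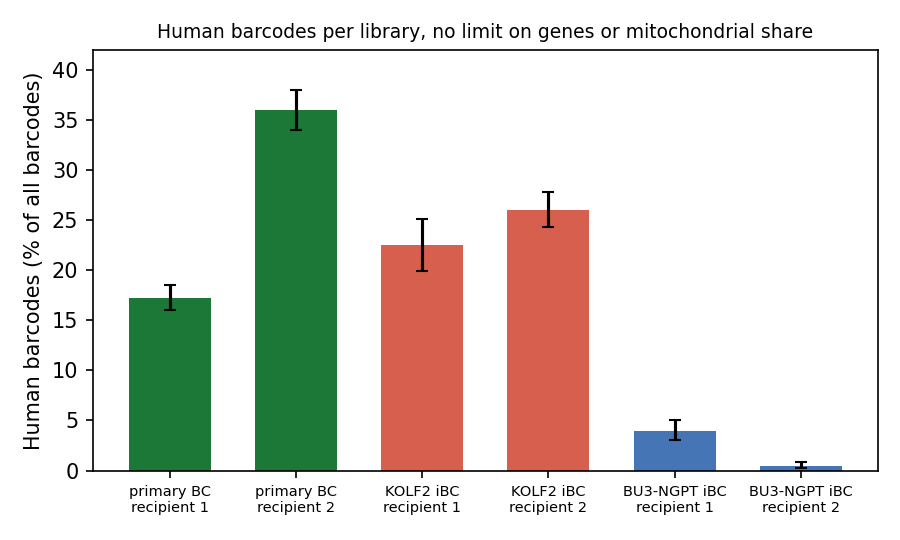
Human barcodes as percent of all barcodes in each of the 6 libraries, with bars for the share and error bars for the 95% exact binomial interval. The BU3-NGPT libraries sit at 3.95% and 0.473%, below the 17.3% to 36.0% of the other libraries.

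BU3-NGPT recipients left too few human cells for any comparison of genes. After the limits fixed before the data were examined (at least 1000 detected genes and at most 20% mitochondrial UMIs), 1 and 2 human cells remained in the BU3-NGPT libraries, against 86 and 126 in the KOLF2 libraries and 69 and 51 in the primary BC libraries. All 3 of the BU3-NGPT cells fell in the multiciliated-like cluster, led by dynein and cilia genes such as DNAAF1 and DNAH12. The multiciliated-like share was 1.19% ± 1.68 (SD, n = 2) in KOLF2 recipients. The cell of the first BU3-NGPT library held 1507 UMIs, of which 0.531% were mitochondrial, near the median of 0.352% in that library's mouse-like barcodes. It was absent, as was 1 cell of the second library, once barcodes with mouse RNA were removed. With a limit of 40% mitochondrial UMIs and such barcodes removed, the first library held 1 cell, in a secretory-like cluster and with 546 SCGB1A1 UMIs, and the second 2 multiciliated-like cells. Basal-like cells were 0.0% in BU3-NGPT against 28.3% ± 10.9 (SD, n = 2) in KOLF2, and secretory-like cells 0.0% against 0.397% ± 0.561 (SD, n = 2). A share of 0 in 1 and 2 cells allows up to 97.5% and 84.2% by the exact binomial interval, so these shares set no limit on the make-up of the BU3-NGPT grafts. No difference between BU3-NGPT and KOLF2 could reach significance, since the smallest p of the exact permutation test, 2-sided, with 2 against 2 libraries is 0.333.

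Under the planned limits, secretory-like cells were scarce in the KOLF2 grafts, at 0 of 86 and 1 of 126 cells. The BU3-NGPT libraries entered the mean over both iPSC lines with 0 of 1 and 0 of 2 cells, which show no scarcity by themselves. With each library weighted equally, secretory-like cells were 0.198% ± 0.397 (SD, n = 4) of iBC-derived cells and 47.5% ± 7.72 (SD, n = 2) of primary BC-derived cells. The difference was -47.3 percentage points (2-sided exact permutation p = 0.133, the smallest that this test can give with 4 against 2 libraries). The difference narrowed to -18.6 points with finer clusters, to -26.3 by marker score or with up to 40% mitochondrial UMIs, and to -10.04 with no mitochondrial limit. Few BU3-NGPT cells carried most of this. The single cell of the first BU3-NGPT library was secretory-like in the first 3 of these settings, and 1 of 2 cells of the second with finer clusters, while the KOLF2 shares were at most 8.22%. With no limit it was 10 of 16 cells in the first BU3-NGPT library, and the primary shares were 36.0% and 20.7%. Basal-like cells were 14.2% ± 17.5 (SD, n = 4) against 22.3% ± 21.2 (SD, n = 2), a difference of -8.08 points that lay within the spread between libraries (exact permutation p = 0.533). This difference turned to 6.92 points without the second primary BC library. Multiciliated-like cells were 50.6% ± 57.1 (SD, n = 4) against 15.05% ± 7.41 (SD, n = 2), a mean carried by the 3 BU3-NGPT cells (exact permutation p = 0.800), and the difference turned from 35.5 to -3.08 points with a limit of 500 detected genes, and was 19.1 without either BU3-NGPT library. In the primary BC libraries 14 of 69 and 5 of 51 cells were multiciliated-like. Once barcodes with mouse RNA were removed, 4 of 59 and 3 of 49 were.

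The KOLF2 and primary BC grafts were compared on a wider set of cells, up to 40% mitochondrial UMIs and without barcodes that also held mouse RNA. This limit was chosen after the planned limits were seen to remove 81.8% and 91.6% of the primary BC and 58.7% and 75.6% of the KOLF2 human barcodes with at least 1000 genes. It left 132 and 118 primary BC-derived and 126 and 219 KOLF2-derived cells. Secretory-like cells were 54.7% ± 1.89 (SD, n = 2) of the primary grafts and 6.89% ± 1.88 (SD, n = 2) of the KOLF2 grafts. Suprabasal squamous-like cells were 43.3% ± 0.692 (SD, n = 2) of the KOLF2 grafts and 11.4% ± 14.9 (SD, n = 2) of the primary grafts, in which 29 of the 30 such cells came from the first recipient. The KOLF2 cells lay in 2 clusters, named by KRT13, KRT4, SPRR1B and KRTDAP and by SPRR3, IVL, SPRR1B, KRT13 and CNFN. The primary cells lay in another cluster, named by KRT6A, KRT16 and SPRR1B, with the basal markers KRT5 and S100A2 also among its leading genes. The squamous-like difference of 31.9 points became 8.41 with no mitochondrial limit and 56.5 at 20%, and 49.6 and 19.5 with coarser and finer clusters. The primary cells classed as squamous-like, 29 and 1 here, numbered 0 and 0 at 20% and 0 and 1 with coarser clusters. Basal-like cells were 39.2% ± 6.33 (SD, n = 2) in KOLF2 and 25.1% ± 17.3 (SD, n = 2) in primary grafts, and multiciliated-like cells 0.625% ± 0.238 (SD, n = 2) and 7.51% ± 2.23 (SD, n = 2). A cluster led by the proliferation genes TOP2A and MKI67 held 5.56% and 4.11% of the KOLF2 cells and 0.0% and 0.847% of the primary cells, where 0 of 132 allows up to 2.27% in that cluster (3 cells of the total). Cells with at least 3 proliferation markers, whatever their cluster, were 9.52% and 6.39% of the KOLF2 and 6.06% and 6.78% of the primary cells. With 2 recipients per group the exact permutation p was 0.333, the smallest possible, for the secretory-like, squamous-like and multiciliated-like shares, and 0.667 for the basal-like share. Different clusters held the basal-like, squamous-like and, but for 1 primary cell, secretory-like cells of the 2 groups, while the multiciliated-like cells of both lay in 1 cluster. The secretory-like difference narrowed from -47.8 to -13.3 points with finer clusters, where 2 clusters of 50 and 37 primary cells, with SERPINB3 and AQP5 among the leading genes of both, stayed unnamed. It was -15.2 with coarser clusters, -19.7 with at least 2000 genes and -22.98 with no mitochondrial limit. The basal-like difference of 14.1 points turned to -4.72 with no mitochondrial limit, and was 1.89 and 26.3 without the first and the second primary BC recipient.

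**Figure D2:**
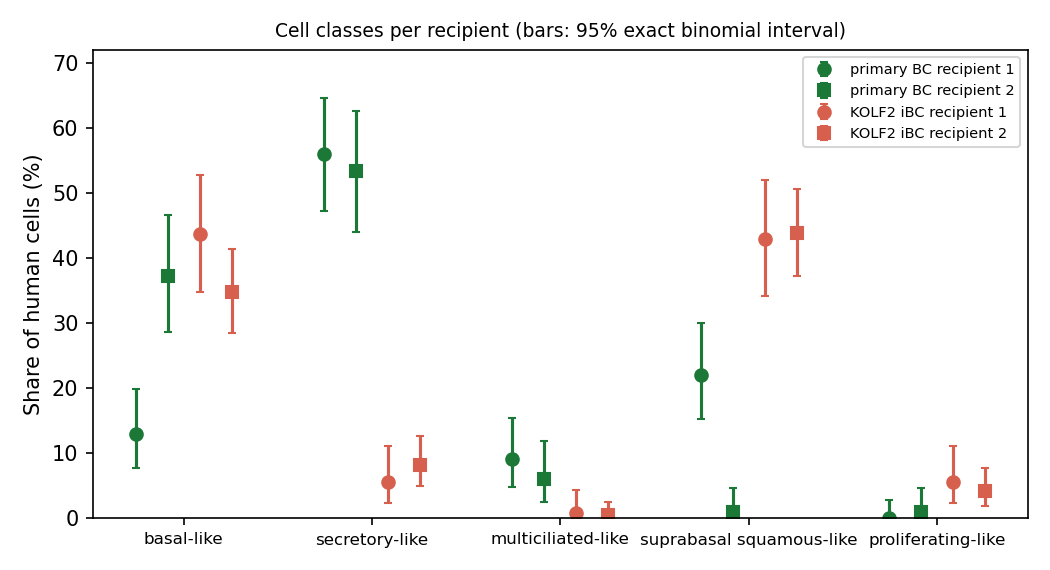
Share of human cells in each class, in percent, for the 2 primary BC and 2 KOLF2 recipients, on cells with up to 40% mitochondrial UMIs, with error bars for the 95% exact binomial interval. Secretory-like cells lie at 56.1% and 53.4% in primary BC and at 5.56% and 8.22% in KOLF2 recipients.

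Taken as whole grafts, KOLF2-derived cells carried high levels of fetal and squamous genes and little of the secretory and ciliary programme. All human cells of a library that passed the planned limits were summed, giving 702730 and 664420 UMIs for primary BC and 2296959 and 1828599 for KOLF2. Group levels are given as CPM, UMI counts scaled by library size and TMM, and levels of single libraries in the text as CPM without TMM. Folds are edgeR's fitted values, which can differ from the ratio of 2 mean CPM where counts are low. Of 9996 genes, 737 were higher and 958 lower in KOLF2 grafts at an adjusted p under 5% (edgeR's quasi-likelihood test, Benjamini-Hochberg, 2 against 2 recipients). IGF2, a fetal growth factor from an imprinted locus (ENSG00000167244), had 0 UMIs in the primary grafts and 1114 ± 183 CPM (SD, n = 2) in KOLF2, at least 480-fold higher against a floor of 3 UMIs over the group. Its imprinted neighbour H19 (ENSG00000130600), a non-coding RNA, rose from 267 ± 28.8 to 7701 ± 797 CPM (SD, n = 2; adjusted p = 2.53e-07, edgeR). The RNA-binding proteins IGF2BP3 (30.2-fold, adjusted p = 1.28e-05, edgeR) and IGF2BP1 (at least 17.2-fold) rose with them. Of 9 tested genes of the list of fetal and imprinted genes, 8 rose and 0 fell, and the same numbers were found adjusted over the list alone. The list passed camera, a test of a gene list against the other genes (adjusted p = 9.68e-21 with a preset correlation of 0.01; adjusted p = 0.135 with an estimated correlation).

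Some squamous markers and both subunits of calprotectin rose in the same grafts. KRT13, a keratin of non-keratinising stratified epithelium, rose from 410 ± 490 to 10709 ± 96.0 CPM (SD, n = 2; adjusted p = 0.00171, edgeR), KRT4 4.63-fold (adjusted p = 0.00174, edgeR) and SPRR3 13.7-fold (adjusted p = 1.51e-05, edgeR). The cornified envelope precursor IVL was higher by a ratio of 37.3, with a counting interval of 12.7 to 182 since primary grafts held 3 UMIs. Of 8 tested suprabasal squamous markers 4 rose and 1 fell, the same numbers adjusted over the list alone (camera adjusted p = 2.00e-05; adjusted p = 0.348 with an estimated correlation). The calprotectin subunits S100A8 and S100A9 rose 1387-fold and 95.5-fold (edgeR adjusted p = 4.55e-07 and 1.43e-06). Primary grafts held only 6 and 0 S100A8 UMIs on the wider set of up to 40% mitochondrial UMIs, so the size of its fold is uncertain. RHCG, an ammonium transporter, and TMPRSS11B, a serine protease, had 0 UMIs in primary grafts and were at least 227-fold and 129-fold higher. The transcription factor BARX1 also had 0 UMIs in primary grafts, and was at least 31.5-fold higher. Of 6 tested WNT genes 3 rose, among them the ligands WNT5A (20.7-fold), WNT4 (2.09-fold) and WNT7B (1.79-fold), and 1, DKK3, fell 5.29-fold (adjusted over the list alone 3 and 1; camera adjusted p = 0.0379; adjusted p = 0.456 with an estimated correlation). This list call ended without the first primary BC or either KOLF2 recipient, with no low-count filter, with at least 500 genes and with up to 40% or no limit on mitochondrial UMIs, and with a minimum count of 30 or after thinning the list had too few genes to test. Of 22 nuclear genes of oxidative phosphorylation 4 rose, with COX6A1 at 1.80-fold and UQCRH at 1.70-fold, and 0 fell (adjusted over the list alone 9 and 0; camera adjusted p = 0.00364; adjusted p = 0.695 with an estimated correlation).

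Secretory and ciliary genes fell in KOLF2 grafts. SCGB1A1, the club cell secretoglobin, fell from 22275 ± 4916 to 49.6 ± 26.8 CPM (SD, n = 2; adjusted p = 4.55e-07, edgeR), and SCGB3A1 from 5077 ± 3247 to 8.38 ± 9.31 CPM (adjusted p = 1.28e-05, edgeR). BPIFB1, an airway defence protein, had 0 UMIs in KOLF2 grafts and was at least 347-fold lower, and the mucin MUC5AC was lower by a ratio of 300 (counting interval 102 to 1462). Of 13 tested secretory markers 0 rose and 11 fell (the same numbers adjusted over the list alone; camera adjusted p = 9.24e-24; adjusted p = 0.135 with an estimated correlation). All 13 tested multiciliated markers fell, also adjusted over the list alone, with RSPH1 48.2-fold and PIFO 25.4-fold lower (camera adjusted p = 1.75e-13; adjusted p = 0.348 with an estimated correlation). FOXJ1, the master regulator of motile cilia, was lower by a ratio of 136 (counting interval 23.2 to 5481). These falls went with the class make-up, since secretory-like cells were 42.03% and 52.9% of the primary cells summed here and 0.0% and 0.794% of the KOLF2 cells. The primary sums held 14 and 5 multiciliated-like cells, and 4 and 3 once barcodes with mouse RNA were removed. The list of multiciliated markers still passed camera without those barcodes. The 20% limit left out most KOLF2 secretory-like cells, which were 5.56% and 8.22% on the wider set and lay in a cluster with a median of 33.1% mitochondrial UMIs. On that set the first KOLF2 graft held SCGB1A1 at 34.1 and SCGB3A1 at 1.38 CPM and the second at 2782 and 356 CPM. With up to 40% mitochondrial UMIs the log2 fold change of SCGB1A1 shrank from -8.83 to -4.05 (adjusted p = 0.0185, edgeR), that of SCGB3A1 from -9.33 to -5.05, that of MUC5AC from -8.01 to -6.41 and that of BPIFB1 to -4.10. With no limit SCGB1A1 stood at -4.24 and did not pass (adjusted p = 0.0503, edgeR).

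Most tested detoxification genes and some ion transport genes fell too. ALDH1A1 was 78.3-fold lower (adjusted p = 7.06e-07, edgeR), ADH7 22.6-fold and GSTA1 15.5-fold. Of 17 tested genes of xenobiotic metabolism and the NRF2 response 1 rose and 13 fell (the same numbers adjusted over the list alone; camera adjusted p = 4.29e-20; adjusted p = 0.135 with an estimated correlation). The water channel AQP5 was 61.2-fold and the sodium channel subunit SCNN1A 6.89-fold lower. Of 10 tested ion transport genes 1 rose and 5 fell (the same numbers adjusted over the list alone; camera adjusted p = 1.07e-05; adjusted p = 0.187 with an estimated correlation). ALDH1A1, ADH7, GSTA1 and AQP5 are among the leading genes of secretory-like clusters, so class make-up enters these folds. The xenobiotic list also passed camera as lower within basal-like and secretory-like cells, and the ion transport list within basal-like cells only. The alarmin IL33 and the transcription factor TCF4 were lower by ratios of 400 (counting interval 110 to 3319) and 359 (98.3 to 2982). KRT14 rose from 92.9 ± 68.3 to 1898 ± 1058 CPM (SD, n = 2; adjusted p = 2.10e-04, edgeR), and SOX2, a foregut transcription factor, fell 2.57-fold (adjusted p = 0.00118, edgeR). The list of basal markers did not pass (median log2 fold change 0.16, mean -0.46, camera adjusted p = 0.875). KRT15 was at 691 ± 146 CPM in primary and 690 ± 15.2 CPM in KOLF2 grafts, and KRT5, TP63 and the lung transcription factor NKX2-1 did not pass either (adjusted p = 0.287, 0.638 and 0.191, edgeR). The count of changed genes fell to 1038 without the first KOLF2 recipient, to 1126 after thinning and to 946 with DESeq2's Wald test. It rose to 2667 without a count filter and to 2826 with no mitochondrial limit. The 2 recipients of a group are separate mice, but no separate donors or cultures are named, so p-values measure the spread between recipients only, and reporter, donor and cell source differ together between the groups.

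Basal-like cells were compared within their class, on 17 and 44 primary BC-derived and 55 and 76 KOLF2-derived cells, which sum to 160809, 516336, 1122880 and 822754 UMIs. The primary cells all lay in a cluster led by IL33 and LGALS1. The KOLF2 cells lay in 1 cluster led by SPARC and COL17A1 and another led by MT1X and LY6D. KOLF2 basal-like cells carried squamous keratin and fetal transcripts that primary basal-like cells nearly lacked. KRT13 (ENSG00000171401), with 4 and 3 UMIs in the primary recipients, rose from 16.2 ± 14.2 to 5551 ± 559 CPM (SD, n = 2; adjusted p = 1.92e-09, edgeR), and KRT4 8.73-fold to 1426 ± 290 CPM (adjusted p = 1.17e-05, edgeR). Every KOLF2 basal-like cell, 55 and 76, held KRT13 UMIs, against 4 of 17 and 2 of 44 primary ones, at median depths of 19089 and 9674 against 7523 and 11544 UMIs. In the first primary BC recipient 27 of 29 squamous-like cells also held KRT13 UMIs, at a median of 1303 CPM. Their cluster had KRT5 and S100A2 among its leading genes but was named squamous-like. The near absence of KRT13 in primary basal-like cells thus depends in part on how clusters were named. Squamous-like cells of the KOLF2 libraries held KRT13 at 14098 and 12547 CPM, and mouse-like barcodes of the same libraries at 623 and 633 CPM, with a KRT13 UMI in 82.7% and 70.5% of them at median depths of 5641 and 2752 UMIs. Mouse-like barcodes of the other libraries held KRT13 at a like level, 654 and 441 CPM with primary BC and 806 and 818 CPM with BU3-NGPT, with a UMI in 64.8% to 70.3% of them.

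H19 rose 85.9-fold to 4193 ± 985 CPM (SD, n = 2; adjusted p = 3.84e-08, edgeR) in basal-like cells, and IGF2 was at least 155-fold higher, at 711 ± 34.2 CPM. PEG10, an imprinted gene, rose 5.97-fold (adjusted p = 2.85e-04, edgeR). Of 9 tested fetal and imprinted genes 6 rose and 0 fell (7 and 0 adjusted over the list alone; camera adjusted p = 1.25e-17; adjusted p = 0.235 with an estimated correlation). BARX1, the serine protease TMPRSS11A and the serotonin transporter SLC6A4 had 0 UMIs in primary basal-like cells, and were at least 25.2-fold, 63.7-fold and 10.9-fold higher. Of 5 tested squamous markers 2 rose and 0 fell, namely KRT13 and KRT4 (the same numbers adjusted over the list alone), while KRT6A was at 84.3 ± 8.13 and 56.8 ± 46.3 CPM (SD, n = 2). The median log2 fold change of this list was 0.23 and its mean 2.08 (camera adjusted p = 1.71e-07; adjusted p = 0.235 with an estimated correlation). Of 7 tested mucosal defence genes 4 rose and 1 fell, with S100A8 at least 194-fold and DEFB1 16.7-fold higher and CXCL1 18.4-fold lower (4 and 2 adjusted over the list alone; camera adjusted p = 4.64e-05; adjusted p = 0.235 with an estimated correlation). KOLF2 basal-like cells held 24.6 and 4.24 S100A8 UMIs per cell and 21.0 and 16.3 S100A9 UMIs, against 0.200 and 0.175, and 0.395 and 0.701, per mouse-like barcode of the same libraries. Of these UMIs 88.8% to 95.4% lay in the 6 of 55 and 8 of 76 cells with most of them, against 32.4% and 38.8% for KRT13.

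**Figure D3:**
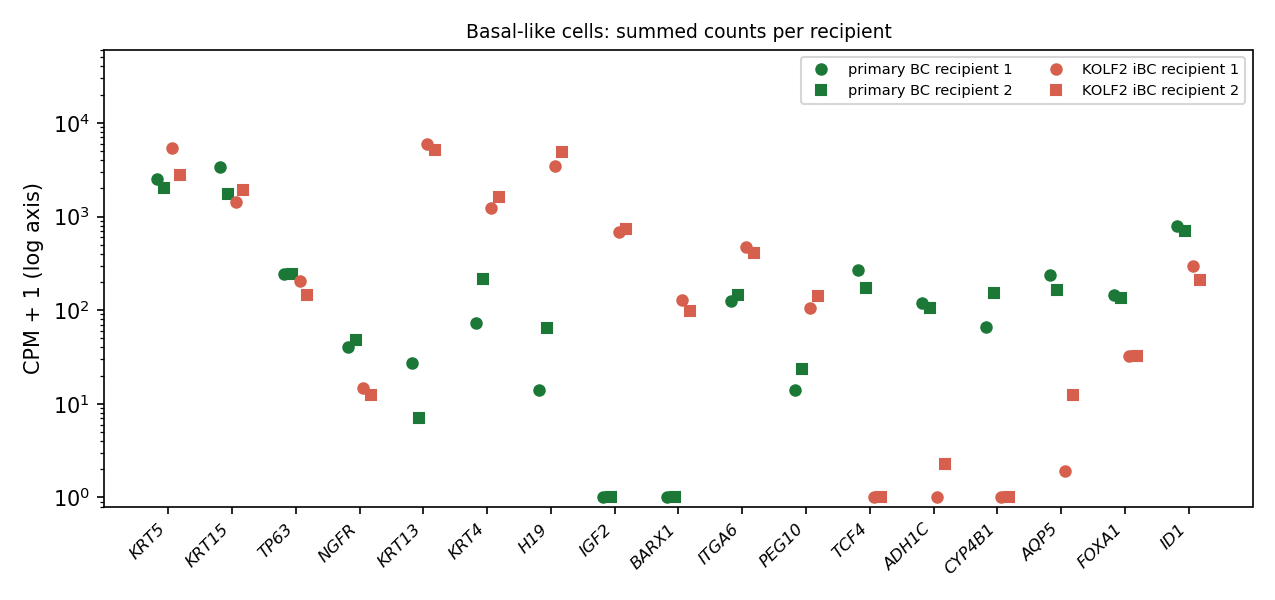
CPM scaled by TMM, plus 1, on a log axis, of selected genes in basal-like cells of each recipient, with circles for the first and squares for the second recipient of each group. KRT13, H19, IGF2 and BARX1 lie higher in both KOLF2 recipients, and TCF4, ADH1C, CYP4B1 and AQP5 lower, than in both primary BC recipients.

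Genes that were higher in KOLF2 basal-like cells included some of cell anchorage. The laminin receptor subunit ITGA6 rose 3.22-fold to 440 ± 46.9 CPM (SD, n = 2; adjusted p = 2.04e-04, edgeR) and NPNT 3.58-fold (adjusted p = 3.38e-04, edgeR). Of 19 tested hemidesmosome and basement membrane genes 8 rose and 0 fell (9 and 1 adjusted over the list alone; camera adjusted p = 8.55e-04; adjusted p = 0.270 with an estimated correlation). FRAS1, COL7A1 and COL17A1 of that list lead a KOLF2 cluster. Without them 5 of 16 rose and 0 fell (6 and 1 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.111; adjusted p = 0.377 with an estimated correlation). Of 22 oxidative phosphorylation genes 2 rose, COX5B and COX6A1 (1.82-fold and 1.95-fold), and 0 fell (the same numbers adjusted over the list alone; camera adjusted p = 0.00638; adjusted p = 0.707 with an estimated correlation). Over all classes of this set, median mitochondrial shares were 14.5% and 17.6% in KOLF2 and 21.9% and 21.7% in primary BC grafts.

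Genes that were lower in KOLF2 basal-like cells included some lung and foregut factors, BMP targets and xenobiotic enzymes. FOXA1 fell 4.38-fold, from 140 ± 6.32 to 31.4 ± 0.450 CPM (SD, n = 2; adjusted p = 9.63e-05, edgeR), with FOXP2 (3.28-fold) and SOX9 (5.68-fold). Of 10 tested lung and foregut transcription factors 0 rose and 3 fell (0 and 4 adjusted over the list alone; camera adjusted p = 0.00220; adjusted p = 0.236 with an estimated correlation). NKX2-1 and SOX2 did not pass (adjusted p = 0.239 and 0.247, edgeR). ID1, a direct target of BMP signalling, fell 2.90-fold (adjusted p = 3.03e-04, edgeR) and ID4 3.61-fold. Of 11 tested BMP and TGF-beta genes 2 rose and 4 fell (2 and 6 adjusted over the list alone; camera adjusted p = 0.00771; adjusted p = 0.235 with an estimated correlation). The cytochrome CYP4B1 had 0 UMIs in KOLF2 basal-like cells and was at least 80.5-fold lower, ADH7 was 17.4-fold lower. Of 13 tested xenobiotic genes 2 rose and 7 fell (2 and 8 adjusted over the list alone; camera adjusted p = 9.60e-15; adjusted p = 0.235 with an estimated correlation). AQP5 was 33.6-fold lower and SCNN1A lower by a ratio of 42.1 (counting interval 13.5 to 212). Of 8 tested ion transport genes 0 rose and 3 fell (1 and 4 adjusted over the list alone; camera adjusted p = 7.71e-05; adjusted p = 0.235 with an estimated correlation). TCF4 was at least 119-fold lower, the protease PRSS23 55.0-fold and the hypoxia factor EPAS1 20.9-fold lower (adjusted p = 3.84e-08 and 3.67e-07 for the last 2, edgeR). Of 5 tested secretory markers 3, SCGB1A1, SCGB3A1 and WFDC2, were lower and 1, MUC16, was higher by a ratio of 8.70 (counting interval 2.29 to 73.8), but lower, by a log2 fold change of -1.62, when cells were classed by marker score, and it did not pass in 6 other alternatives. Adjusted over the list alone 1 rose and 4 fell (camera adjusted p = 4.22e-07; adjusted p = 0.235 with an estimated correlation). SCGB1A1 was at 4.12 and 7.48 UMIs per primary basal-like cell and 3.68 and 8.17 per mouse-like barcode of the same libraries, and at 0.473 and 0.566 against 0.542 and 0.583 in the KOLF2 libraries. SCGB3A1 was at 2.24 and 1.89 against 1.84 and 2.04, and at 0.0545 and 0.132 against 0.0761 and 0.152. Each mouse-like value lay within the 95% Poisson interval of the basal-like one, so SCGB1A1 and SCGB3A1 are read as background in this class, and without them the list has too few genes to test. WFDC2 was at 137 and 217 CPM in primary and 11.6 and 57.1 CPM in KOLF2 basal-like cells. Mouse-like barcodes of these libraries held it at 4107 to 5336 CPM, so background is not excluded for WFDC2 either.

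Of 12 tested basal markers 3 rose and 4 fell in basal-like cells, the same numbers adjusted over the list alone. Without the 5 that lead a cluster of the class (COL17A1, IL33, KRT14, KRT17 and S100A2) 1 of 7 rose and 2 fell. The whole list did not pass, with a median log2 fold change of -0.45 and a mean of -0.72 (camera adjusted p = 0.128; adjusted p = 0.356 with an estimated correlation). KRT15, at 2554 ± 1146 and 1691 ± 348 CPM, and TP63, at 243 ± 0.944 and 173 ± 40.6 CPM (SD, n = 2), did not pass (adjusted p = 0.201 and 0.256, edgeR). The receptor NGFR fell 3.49-fold (adjusted p = 0.00792, edgeR), and KRT5 passed at 1.83-fold (adjusted p = 0.0403, edgeR), a call that ended in 7 of the alternative settings, among them 0.34 on the log2 scale without the first KOLF2 recipient (adjusted p = 0.448, the highest of them, edgeR). In all, 372 genes were higher and 423 lower of 7656 tested, 37 of which lead a cluster of the class. After thinning every library to the lowest total count 315 genes passed, without the second primary BC recipient, which leaves 17 primary cells, 341, and with DESeq2's Wald test 368. With at most 20% mitochondrial UMIs 472 passed, and 518 with a minimum count of 30. Of the list calls in basal-like cells, that of mucosal defence ended without either primary BC or the second KOLF2 recipient, with no low-count filter, with at least 500 genes, by marker score and with no mitochondrial limit. That of oxidative phosphorylation ended without the first KOLF2 recipient, with a minimum count of 30, after thinning and with at least 500 genes, and that of hemidesmosome genes at 20% and with no mitochondrial limit. That of lung and foregut factors ended after thinning, and that of BMP and TGF-beta genes with a minimum count of 30, after thinning, with at least 500 or 2000 genes, by marker score and at 20% or no mitochondrial limit.

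Secretory-like cells were compared on 74 and 63 primary BC-derived cells, with 695268 and 930998 UMIs, and only 7 and 18 KOLF2-derived cells, with 142314 and 227420 UMIs. The primary cells, all but 1, lay in clusters led by SERPINB3 and AQP5 and by MUC5AC and BPIFB1, and the KOLF2 cells in a cluster led by SCGB3A2, SAA1 and LCN2 whose cells held a median of 33.1% mitochondrial UMIs, against 20.2% and 28.5% in the primary clusters. The 7 cells of the first KOLF2 recipient held 5 SCGB1A1 UMIs and 0 UMIs of SCGB3A1, SCGB3A2 and MUC5AC. They held S100A9 at 9720.5 and KRT13 at 4997 CPM. In the second KOLF2 recipient 13 of 18 cells held SCGB1A1 UMIs. The class of the 7 cells thus rests on the name of their cluster. Whether the differences below are in part differences in cell type was not tested. Alveolar type 2 markers were seen beside the secretory ones mainly in the second KOLF2 recipient, and are named here after their values were seen. Cells of any class with at least 3 such markers numbered 2 of 219 in that recipient and 0 of 126 in the first. In the primary BC recipients they numbered 1 of 132 and 0 of 118. The surfactant protein gene SFTPA2, among the leading genes of the KOLF2 cluster, was at 14.1 and 2885 CPM in KOLF2 secretory-like cells (2 and 656 UMIs) and SFTPB at 0.0 and 990 CPM (0 and 225 UMIs), each with 0 UMIs in both primary recipients. SFTPC had 0 UMIs in all 4. None of these genes passed the count filter, so they were not tested. Genes that were higher in KOLF2 secretory-like cells included some interferon response and antigen presentation genes. The interferon-induced genes BST2 (8.28-fold, adjusted p = 0.00156, edgeR), EPSTI1 (8.86-fold) and OAS1 (3.61-fold) rose. Of 17 tested interferon response genes 7 rose and 0 fell (11 and 0 adjusted over the list alone; camera adjusted p = 2.26e-06; adjusted p = 0.245 with an estimated correlation). B2M, the light chain of class I HLA, rose 2.08-fold from 848 ± 27.4 to 1761 ± 229 CPM (SD, n = 2; adjusted p = 0.00665, edgeR), with TAPBP at 2.25-fold and IRF1 at 3.22-fold. Of 9 tested antigen presentation genes 6 rose and 0 fell (the same numbers adjusted over the list alone; camera adjusted p = 3.90e-04; adjusted p = 0.223 with an estimated correlation). B2M missed the threshold in 6 alternatives, with an edgeR adjusted p of up to 0.353 at finer clusters, where its log2 fold change was 0.46. Of 15 tested mucosal defence genes 8 rose and 1 fell (8 and 2 adjusted over the list alone; camera adjusted p = 3.21e-06; adjusted p = 0.266 with an estimated correlation), with S100A9 85.7-fold higher at 7768 ± 2915 CPM (adjusted p = 9.86e-05, edgeR).

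Most tested fetal and squamous genes rose in secretory-like cells as well. IGF2 was at least 108.5-fold higher, H19 10.2-fold higher at 3239 ± 174 CPM (SD, n = 2; adjusted p = 5.37e-04, edgeR). Of 6 tested fetal and imprinted genes 5 rose and 0 fell (the same numbers adjusted over the list alone; camera adjusted p = 1.69e-10; adjusted p = 0.185 with an estimated correlation). KRT13 rose 48.2-fold to 4300 ± 1065 CPM (adjusted p = 2.12e-04, edgeR) and SPRR3 17.8-fold. Of 6 tested squamous markers 4 rose and 0 fell (the same numbers adjusted over the list alone; camera adjusted p = 4.63e-06; adjusted p = 0.245 with an estimated correlation). These genes stood higher in the squamous-like cells of the same KOLF2 libraries, where KRT13 was at 14098 and 12547 CPM and S100A9 at 17789 and 22958 CPM.

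Genes that were lower in KOLF2 secretory-like cells included some xenobiotic enzymes, basal markers, BMP targets and oxidative phosphorylation genes. ADH1C and FMO2 had 0 UMIs in KOLF2 secretory-like cells and were at least 8.94-fold and 10.8-fold lower. Of 14 tested xenobiotic genes 0 rose and 9 fell (the same numbers adjusted over the list alone; camera adjusted p = 1.69e-10; adjusted p = 0.185 with an estimated correlation). The stress protein NUPR1 was at least 20.8-fold lower. KRT5 fell 9.04-fold (adjusted p = 0.00196, edgeR; up to 0.670 in its alternatives, with finer clusters) and S100A2 13.1-fold. Of 7 tested basal markers 0 rose and 3 fell (0 and 5 adjusted over the list alone; camera adjusted p = 1.55e-04; adjusted p = 0.218 with an estimated correlation). ID1 fell 6.48-fold (adjusted p = 0.00117, edgeR) and ID3 was lower by a ratio of 22.1 (counting interval 3.87 to 880). Of 5 tested BMP and TGF-beta genes 0 rose and 2 fell (0 and 3 adjusted over the list alone; camera adjusted p = 0.00332; adjusted p = 0.266 with an estimated correlation). UQCRB fell 2.56-fold (adjusted p = 0.00809, edgeR; up to 0.390 in its alternatives, with finer clusters) and COX7C 1.99-fold. Of 22 oxidative phosphorylation genes 0 rose and 8 fell (0 and 13 adjusted over the list alone; camera adjusted p = 5.27e-06; adjusted p = 0.185 with an estimated correlation). SOX2 fell 3.50-fold (adjusted p = 0.00725, edgeR). Without the leading genes of the class's own clusters, 4 of 9 mucosal defence genes rose and 1 fell, 5 of 8 antigen presentation genes rose and 0 fell, and 0 of 11 xenobiotic genes rose and 6 fell (4 and 2, 5 and 0, and 0 and 6 adjusted over the list alone). These lists still passed (camera adjusted p = 1.49e-04, 0.00121 and 3.52e-05; adjusted p = 0.312, 0.236 and 0.236 with an estimated correlation).

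The secretoglobins did not pass in this class, where the KOLF2 recipients differed. SCGB1A1 had 5 UMIs in the 7 cells of the first KOLF2 recipient and 7141 UMIs in the 18 cells of the second, of which 51.8% lay in 1 cell (adjusted p = 0.659, edgeR). SCGB3A2, a secretoglobin of distal airways, had 1641 UMIs in the second KOLF2 recipient, 99.5% of them in 1 cell, and 0 in the first. In all, 361 genes were higher and 320 lower of 5948 tested, 30 of which lead a cluster of the class, and 29 of the 52 named genes that passed did so in every alternative run. The count fell to 231 and 208 with coarser and finer clusters, to 434 without the first primary BC recipient, to 354 with at least 2000 genes, to 402 after thinning and to 374 with DESeq2's Wald test, and rose to 1104 with no mitochondrial limit. With finer clusters the lists of antigen presentation, mucosal defence, basal markers and oxidative phosphorylation did not pass. That of basal markers did not pass by marker score or without the first KOLF2 recipient either.

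The medians of the fixed lists held when genes with 3 or fewer UMIs in a group were set at their bound, with shifts from 4.85 to 3.96 for fetal genes and from -4.35 to -4.47 for multiciliated markers in all human cells, and from -1.96 to -1.88 for xenobiotic genes in secretory-like cells.

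**Figure D4:**
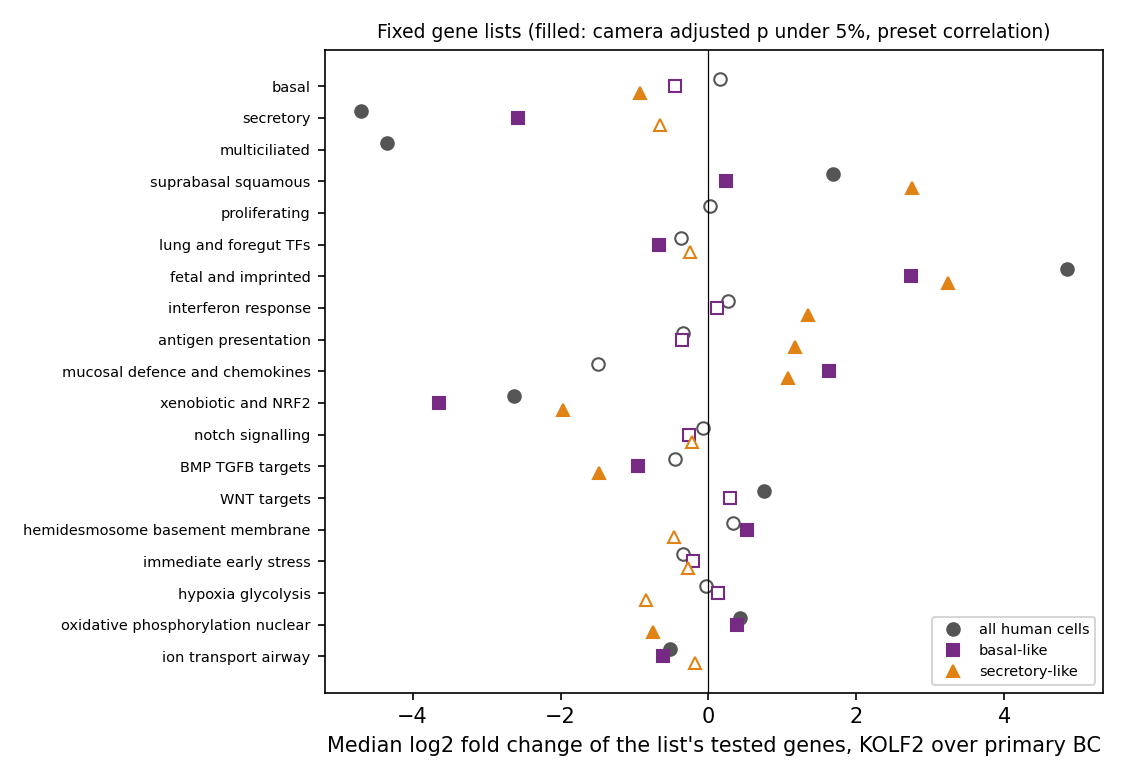
Median log2 fold change, KOLF2 over primary BC, of the tested genes of each fixed list, for all human cells, basal-like and secretory-like cells. Filled symbols passed camera at 5% with a preset correlation, as 8, 10 and 9 lists did, and 0 lists in each comparison passed with an estimated correlation.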

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

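The test of whether the group difference depends on the cell class and the shares of mouse-like barcodes with an SCGB1A1 UMI were chosen after the data were seen. A model with class and group together, on the 4 libraries of KOLF2 and primary BC, passed 548 of 8591 genes at 5% (edgeR with Benjamini-Hochberg), 208 with a higher and 340 with a lower KOLF2 effect in secretory-like than in basal-like cells, with 2 residual degrees of freedom. In this model 8 gene lists passed camera, and their adjusted p with an estimated correlation was 0.328, or 0.356 for the squamous markers. The alternative settings did not cover this model. Within secretory-like cells the calls of oxidative phosphorylation, antigen presentation and mucosal defence genes ended with finer clusters.

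Oxidative phosphorylation genes had the smallest camera p of the 17 lists tested, with a median difference of -1.17 on the log2 scale between the KOLF2 effect in secretory-like and in basal-like cells (camera adjusted p = 4.92e-12). The mitochondrial share was higher in the KOLF2 than in the primary secretory-like clusters. Over all classes its medians were lower in KOLF2 grafts, at 14.5% and 17.6% against 21.9% and 21.7% in primary BC grafts. Whether this goes with the list was not tested. Hemidesmosome and basement membrane genes had a median difference of -0.80 (camera adjusted p = 0.0358), with 3 members that lead a KOLF2 basal-like cluster, hypoxia and glycolysis genes -0.99 (camera adjusted p = 0.0435) and squamous markers -0.79 (camera adjusted p = 0.0472). Antigen presentation genes had a median difference of 1.25 (camera adjusted p = 8.46e-06) and interferon response genes 1.19 (camera adjusted p = 1.30e-04). Mucosal defence genes had a median difference of 1.49 and secretory markers, which name one of the classes, 2.20 (camera adjusted p = 0.0148 for each). In basal-like cells SCGB1A1 and SCGB3A1 were read as background, which was higher in the primary BC libraries. That background by itself makes their KOLF2 effect in basal-like cells negative and raises this difference. The result for secretory markers therefore cannot tell a dependence on class from background.

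SCGB1A1 was seen in barcodes that no comparison between groups used. Of mouse-like barcodes thinned to 1000 UMIs, 69.8% and 75.1% in the primary BC libraries held an SCGB1A1 UMI, against 9.38% and 16.6% in the KOLF2 and 13.7% and 1.44% in the BU3-NGPT libraries, with no barcode left out as shallower. Without thinning these shares were 94.7% and 99.4%, 33.3% and 36.7%, and 31.5% and 2.87%, at median depths of 2479 and 3664, 5641 and 2752, and 2596 and 2385 UMIs.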

How the results depend on the processing

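With 2 recipients per group the shares could not pass a threshold, and leaving out a library assumes that the lone sample varies like the other group. Over the alternatives, counts and shares stayed within their spread or 1.5 times in 159 cases, moved in 73 and reversed in 9. Single named genes kept their direction and their side of the threshold in 2949 cases, came to pass in 47, no longer passed in 143 and reversed in 18. Of named genes that passed, 48 of 56 did so in every alternative in all human cells, 36 of 51 in basal-like and 29 of 52 in secretory-like cells. The mitochondrial limits of 40% and none, the removal or keeping of barcodes with mouse RNA, the 20% limit in the added comparisons, and the lists under other size factors, count filters, thinning and without genes open to free RNA were chosen after seeing the data. Not run were the planned gene and list tests within classes, for want of cells, and, where a library or class had too few cells left, shares for BU3-NGPT with at least 2000 genes or without mouse RNA and the secretory-like genes and lists at 20% mitochondrial UMIs. Where no cause is named, the cause was not tested.

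In all human cells the count of 1695 genes became 946 with DESeq2's Wald test, 2667 without a count filter (more genes tested), 1126 after thinning, 2792 with up to 40% mitochondrial UMIs and 2826 with no such limit, and ranged from 1038 (without the first KOLF2 recipient) to 1921 when a library was left out. The count of 8 lists became 0 with an estimated correlation and 4 with fry, with 7 to 10 under other settings and 8 to 11 when a library was left out. In basal-like cells the count of 795 genes became 368 with the Wald test, 518 with a minimum count of 30 (fewer genes tested), 315 after thinning and 472 at 20% mitochondrial UMIs, and ranged from 341 (without the second primary BC recipient) to 858. The count of 10 lists became 9, without that of hemidesmosome genes, when leading genes of the class's clusters were left out of the lists, a test chosen after seeing the data. It became 0 with an estimated correlation, 1 with fry, 4 after thinning (3 of the 10 not tested), 6 with a minimum count of 30 (2 not tested), 6 with at least 500 genes and 6 with no mitochondrial limit (1 not tested in each), 7 by marker score (1 not tested), 8 at 20% mitochondrial UMIs (6 of the 10, and 2 not tested) and 9 with at least 2000 genes or without genes open to free RNA, with 9 to 10 when a library was left out. In secretory-like cells the count of 681 genes became 374 with the Wald test, 402 after thinning, 354 with at least 2000 genes, 231 and 208 at Leiden resolutions 0.5 and 2.0 and 1104 with no mitochondrial limit, and ranged from 434 (without the first primary BC recipient) to 826. The count of 9 lists became 0 with an estimated correlation, 5 with fry (4 of the 9, and Notch signalling), 5 at resolution 2.0 (3 of the 9), 5 after thinning (4 not tested), 6 with a minimum count of 30 (3 not tested), 6 with at least 2000 genes and 6 at resolution 0.5 (5 of the 9, and 4 not tested, in each), 8 by marker score, 10 with no mitochondrial limit and 13 with no low-count filter, with 9 to 13 when a library was left out.

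Recipient numbers pair no animals, and same-numbered recipients deviated with correlations of -0.0743, -0.0743 and -0.00777 in the 3 comparisons. With the replicate block, 1658, 795 and 580 genes and 10, 10 and 9 lists passed.

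For iBC against primary BC, the basal-like difference of -8.08 points reversed to 1.97 with at least 500 genes and ranged from -23.1 to 6.92, reversed without the second primary BC library. The secretory-like difference of -47.3 became -35.3 with at least 500 genes, -18.6 at resolution 2.0, -26.3 by marker score, -26.3 at 40% and -10.04 with no mitochondrial limit, and ranged from -52.7 to -41.8. At resolution 2.0, by marker score and at 40% this came mainly from 1 or 2 BU3-NGPT cells classed as secretory-like. The multiciliated-like difference of 35.5 reversed to -3.08 with at least 500 genes and became 6.86 at resolution 2.0, 17.98 by marker score, 17.8 at 40% and 23.8 with no mitochondrial limit, ranging from 19.1 to 52.4. For BU3-NGPT against KOLF2, the basal-like difference of -28.3 became -39.9 by marker score and -39.2 at 40%, ranging from -36.05 to -20.6. The secretory-like difference of -0.397 reversed to 0.516 with at least 500 genes, 73.8 at resolution 2.0, 46.5 by marker score, 43.1 at 40% and 25.9 with no limit, ranging from -0.794 to 0. The multiciliated-like difference of 98.8 became 6.62 with at least 500 genes, 24.6 at resolution 2.0, 48.02 by marker score, 49.4 at 40% and 64.6 with no limit, ranging from 97.6 to 100.

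For KOLF2 against primary BC, the basal-like difference of 14.1 reversed to -4.72 with no mitochondrial limit and ranged from 1.89 to 26.3. The secretory-like difference of -47.8 became -45.5 and -19.7 with at least 500 and 2000 genes, -15.2 and -13.3 at resolutions 0.5 and 2.0, -39.02 by marker score, -40.4 with mouse RNA kept, -36.6 at 20% and -22.98 with no limit, ranging from -49.2 to -46.5. Primary BC clusters with SERPINB3 and AQP5 among their leading genes, of 46 cells at 2000 genes, 121 at resolution 0.5, and 50 and 37 at 2.0, held under 3 leading secretory markers and stayed unnamed. At 2.0 a KOLF2 cluster of 44 cells, with a tuft but no squamous marker among its 10 leading genes, stayed unnamed too. The multiciliated-like difference of -6.89 became -9.20 by marker score and ranged from -8.47 to -5.31. The squamous-like difference of 31.9 became 49.6 and 19.5 at resolutions 0.5 and 2.0, 56.5 at 20% and 8.41 with no limit, ranging from 21.4 to 42.5. Primary BC cells of this class numbered 0 and 1 at resolution 0.5 and 0 and 0 at 20%.

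Reversed log2 fold changes of single genes were few. In all human cells, with a library left out, KRT5 ranged from -0.24 (without the first KOLF2 recipient) to 1.19. TP63 ranged from -0.21 (without the first primary BC recipient) to 1.17, and was at -0.03 without the first KOLF2 recipient. KRT15, at -0.0014, turned to 0.12 without a count filter, 0.01373 with the replicate block, 0.069 with at least 500 genes, 0.091 at 40%, 0.27 with no limit, and 0.22 and 0.02 without the second primary BC and the first KOLF2 recipient, in a range from -0.19. In basal-like cells TP63 was at 0.0089 with at least 500 genes, KRT6A from -1.81 to 0.075 with a library left out (reversed without the second KOLF2 recipient), and MUC16 at -1.62 by marker score and -0.45 with no limit. In secretory-like cells NKX2-1 ranged from -6.90 to 0.32 (without the first KOLF2 recipient) with a library left out, and MIR205HG at 0.41 with at least 2000 genes and 0.85 and 1.05 at resolutions 0.5 and 2.0.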

Other observations

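The tests of free RNA, of squamous-like cells for KRT4, S100A8 and S100A9, of class make-up and of the limits on BU3-NGPT cells were chosen after the results were seen. Other cell types were counted per library as human cells with at least 3 markers of a fixed list, in 132 and 118 primary BC-derived and 126 and 219 KOLF2-derived cells. Cells with markers of deuterosomal cells, the precursors of multiciliated cells, numbered 7 and 3 in primary BC and 1 and 3 in KOLF2 grafts. Cells with ionocyte and with neuroendocrine markers numbered 1 each in the first primary BC recipient and 0 in the other recipients, and FOXI1, the ionocyte transcription factor, passed the count filter in no comparison. Cells with tuft markers numbered 0 and 0 in primary BC and 4 and 3 in KOLF2 grafts, where LRMP of that list is among the leading genes of squamous-like clusters. Cells with alveolar type 2 markers numbered 1 and 0 in primary BC and 0 and 2 in KOLF2 grafts. Cells with stromal markers numbered 0 and 1 in primary BC and 3 and 2 in KOLF2 grafts, and COL3A1 and DCN of that list lead the KOLF2 basal-like cluster with SPARC. No cell held at least 3 markers of pluripotent cells, non-lung endoderm, endothelial, immune or glial cells, which allows up to 3 cells of the total, or 2.27%, 2.54%, 2.38% and 1.37% of the 4 grafts. A cluster led by TTN with no marker of any class, of 23 cells at a median of 30.2% mitochondrial UMIs, held 19 cells of the second KOLF2 recipient.

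Among lists that did not pass, the median and the mean or the test pointed opposite ways for notch genes (medians -0.08 in all human and -0.26 in basal-like cells, means 0.05 and 0.25), hypoxia genes in all human cells (median -0.04, tested as up), BMP and TGF-beta genes in all human cells (median -0.46, mean 0.0019) and interferon genes in basal-like cells (median 0.12, tested as down).

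KRT13, KRT4, S100A8 and S100A9 were high in KOLF2 basal-like cells. Free RNA of squamous-like cells is argued against as the source of KRT13, and of KRT4 over the class as a whole. The ratios of these genes to their squamous-like levels were at least 4.08 times the ratio of the 20 genes with the lowest values. For S100A8 and S100A9 such ratios were 0.741 to 1.84 times it, which does not argue against free RNA. Both stood at no less than 23.2 times as many UMIs per basal-like cell as per mouse-like barcode of the same library. In the cluster led by SPARC and COL17A1 they stood at only 0.641 and 0.729 (S100A8) and 1.28 and 1.48 (S100A9) UMIs per cell. Mouse-like barcodes held 0.200 and 0.175, and 0.395 and 0.701. Free RNA is thus argued against for the few cells that hold most of these UMIs, and stays open for the others. A minority of squamous-like cells among the basal-like ones is argued against for KRT13 by its median level per cell, which was at least 2220 CPM in the cluster led by SPARC and COL17A1. For S100A8 and S100A9 such cells may be the source, since at least 88.8% of their UMIs lay in the 6 of 55 and 8 of 76 cells with most of them, and for KRT4, with 46.1% and 54.5% in as many cells, this cannot be told apart from expression by basal-like cells, as the values lie on both sides of 50%. Expression of S100A8 and S100A9 by a few basal-like cells, and a difference of KOLF2 basal cells in keratin programme as a property of line or derivation, stay open and untested.

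H19 and IGF2 were higher in KOLF2 cells in all 3 comparisons. Mouse RNA is argued against, since mouse-like barcodes held these genes at no more than 2.27% of the human level in the KOLF2 libraries. Class make-up is argued against by a smallest log2 fold change of 3.35 within basal-like and secretory-like cells, and the depth gap by a smallest log2 fold change of 3.26 after thinning. The donor, the line, its derivation and the reporter differ together between the groups, so which of them may go with the change was not tested.

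Few human cells were found in the BU3-NGPT libraries. The limits on mitochondrial share and detected genes are argued against as the only cause, since without any limit the human share was at most 3.95%. They did lower the counts. Of 59 and 11 human barcodes, 16 and 2 held at least 1000 genes, and 16 and 1 of these held over 20% mitochondrial UMIs. The number of sorted human cells and of mouse cells added is not given per library in the sources used here, so a lower engraftment and a different sort or mixture may each lie behind the low share, and both stay untested.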
